A study of Mus musculus with 9 samples.

How the data were processed

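The data came from total RNA sequencing of splenic CD3+ T cells of female F1 mice, which were bred from C57BL/6 mothers heterozygous for a deletion of Xist and castaneus fathers. In such animals the choice of the inactive X chromosome is skewed. The labels define 3 groups of 3 libraries. Unstimulated cells were taken into TRIzol straight after enrichment on columns. Stimulated cells were cultured for 48 hours with plate-bound anti-CD3 at 1 µg/ml and soluble anti-CD28 at 10 µg/ml. Cells of the third group had the same culture with IMD-0354 at 2.5 µM, a small molecule that inhibits the kinase IKK-beta upstream of NF-kB. Neither a vehicle in the stimulated cultures nor cultured cells without stimulation are named in the labels, so that culture and stimulation cannot be separated in these samples. The libraries were made with an Illumina kit that keeps strand and depletes ribosomal RNA, per the labels' protocols.

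The values were whole-number read counts per gene in a single deposited table of 49671 genes and 9 libraries, with no normalization by the authors visible in them. Per the submitters' processing notes, STAR 2.7.1a and featureCounts were used with the mm10 build. The annotation release, the strand setting and whether both mates of a fragment were counted are not given in the sources used here. Without a stated strand setting, reads of genes that overlap in opposite directions, such as Xist and Tsix, cannot be told apart with certainty. Between 70.6% and 78.5% of the counts from 1 to 10 were even in each library, a sign that each fragment was largely counted as 2 reads, and intervals drawn from the counts would then be too narrow. The reads of a castaneus genome were compared with a C57BL/6 reference, which can lower the counts of genes with many differences. Of the gene identifiers, 49412 were in GENCODE M21, which was used for gene names, positions and types on the same assembly. The other 259 carried at most 0.036% of a library's counts and kept no name. No count was present in any library for 15400 genes, and 0 columns of the table were left unused. The table has no allele-resolved values, which were not analysed here.

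Total counts ranged from 34009988 to 56221174 per library, and at this depth 3 counts over a group of 3 libraries corresponded to 0.0226 CPM in the unstimulated, 0.0205 in the stimulated and 0.0228 in the inhibitor group. Such floors cover counting error only and take each count as a separate fragment. Where both mates of a fragment were counted, they are too low. Libraries of the same group differed far beyond sampling noise (chi-square per degree of freedom 32.7 to 132), so that each of the 9 was counted as a separate sample. The labels call them biological replicates and do not say that they came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

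Genes were kept with the filterByExpr function of edgeR 4.0.16 (R 4.3.3), which left 18374. Scaling used TMM factors, between 0.925 and 1.122. All 9 libraries entered a single quasi-likelihood fit (glmQLFit, glmQLFTest) with the group as its only term and 6 residual degrees of freedom, and p-values from two-sided tests were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. The 3 comparisons were stimulated against unstimulated, inhibitor against stimulated, and inhibitor against unstimulated. A gene "rose", "fell" or was "called" below only where its adjusted p passed this threshold. Levels are given as CPM (counts scaled to library size, with TMM factors) as mean ± SD over the 3 libraries of a group. Fold changes are log2 values. Where a ± follows them it gives an approximate SE, the size of the fold change over the square root of the test's F statistic. It is not a standard error fitted for the fold change and is least certain for genes near 0 in a group. Fitted fold changes of genes with 0 counts in a group depend on the prior count.

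The tests, the 25 gene lists, the rule for named genes and 20 of the 22 alternative settings were chosen before the data were examined. The lists were NF-kB target genes, T cell activation markers, cytokines and cytotoxic effectors, naive and quiescence genes, cell cycle genes, replication-dependent histone genes, glycolysis genes, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, cholesterol synthesis genes, amino acid stress response genes (targets of ATF4), unfolded protein response genes, ribosome biogenesis genes, interferon-stimulated genes, p53 and apoptosis genes, Xist RNA and X inactivation factors, genes known to escape X inactivation, X-linked immune genes, regulatory T cell genes, CD4 lineage genes, CD8 lineage genes, and markers of B cells, of myeloid and dendritic cells, of NK cells, and of erythroid cells and platelets. Another 3 lists, of hypoxia response, immediate early and T cell genes, were added after the data had been seen and are used in the closing section only. Some lists share members, among them Ccl3, Ccl4, Tnf and Lta in the NF-kB and cytokine lists and Gzma and Eomes in the NK list and others.

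Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation preset at 0.01, adjusted over 75 tests (25 lists in 3 comparisons). The 3 lists added later were adjusted apart, over their own tests only. Beside the count of members called over all genes, a count adjusted over the list alone was made. With an inter-gene correlation estimated from the data, 0 of the list calls passed the threshold in camera, the lowest adjusted p being 0.109 for stimulation, 0.109 for the inhibitor and 0.0839 for the inhibitor against unstimulated cells; 7, 3 and 8 lists had an unadjusted p under the threshold. All X-linked genes were tested with camera as 1 set against all other genes tested, adjusted over the 3 comparisons alone. Their median change was set against that of autosomal genes. The text names Xist, Nfkbia, Il2ra, Cd69 and Mki67 always; the 6 genes with the largest change in each direction among called genes with a mean log2 CPM of at least 3 over the 6 libraries compared, no overlap of the replicates and a symbol that is not that of a predicted gene; and, for each called list, the 2 members with the lowest p in the list's direction and the member with the lowest p in the other direction if called. Other genes named were chosen after their values were seen.

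The alternatives were other scaling (DESeq2 size factors, upper quartile), no count filter, at least 10 CPM in 3 libraries, DESeq2 1.42.0 and limma voom in place of edgeR, the replicate number as a block, only the compared groups in the fit, a minimum fold of 2, mitochondrial genes left out, an estimated correlation, and each of the 9 libraries left out in turn. The other two settings were added after seeing the data: 2 libraries per group (without unstimulated 2, stimulated 1 and inhibitor 1) and leaving out Gm26917, Gm42418, mitochondrial rRNA and Rpph1.

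The steps were tested on simulated counts drawn from the real means over all 9 libraries and the real library sizes. Only 62 to 66 of the genes tested were changed at each fold, whereas 66% of genes were called for stimulation in the data. Recovery and the share of false calls depend on that fraction, so the shares below do not carry over to the data. For stimulation, 7.6%, 37.9% and 61.5% of genes changed by 1.5, 2 and 4-fold were recovered among 17838 tested, and 2.8% of calls were false. For the inhibitor the shares were 12.9%, 50.0% and 73.8% among 17858 genes, with 4.3% false, and for the inhibitor against unstimulated cells 3.1%, 53.0% and 60.6% among 17862, with 4.9% false. A changed list was called in each comparison, and 0 of 50 unchanged lists were. The simulated genes were drawn independently of each other, so this cannot show how the test treats lists of correlated genes. Because the comparisons share libraries, 20 data sets without any effect were simulated for the share of opposite signs and the overlap of calls. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.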

Results

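Gene-level read counts were compared between 3 groups of splenic CD3+ T cells from female F1 mice: unstimulated, stimulated for 48 hours through CD3 and CD28, and stimulated for 48 hours with the IKK-beta inhibitor IMD-0354 (n = 3 libraries each). The title of the series places the experiment in a study of how NF-kB signalling bears on Xist RNA and on the maintenance of X inactivation after T cell activation. Total counts were 38706313, 38438379 and 46782269 in unstimulated libraries 1 to 3. They were 49735319, 50001269 and 56221174 in the stimulated libraries and 34009988, 47904871 and 51508144 in the inhibitor libraries. Inhibitor library 1 had counts in 30106 genes, against 20547 to 23223 in the other 8 libraries. In a principal component analysis the first component (66.4% of the variance) placed the groups apart, with unstimulated libraries at -166 to -145, inhibitor libraries at 24.1 to 54.9 and stimulated libraries at 111 to 115. Inhibitor library 1 lay at -76.7 on the third component (4.9% of the variance), apart from 29.7 and 33.2 for the other inhibitor libraries. The genes that follow most closely from the question were Nfkbia (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647), Il2ra (ENSMUSG00000026770, chromosome 2, 11642807 to 11693193), Cd69 (ENSMUSG00000030156, chromosome 6, 129267325 to 129275436) and Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), all on mm10, beside Xist.

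The first comparison asked how T cells stimulated for 48 hours differed from cells taken straight from the spleen. Il2ra, the alpha chain of the IL-2 receptor, rose from 22.7 ± 2.23 to 1518 ± 62.9 CPM, and Gzmb, a protease of cytotoxic granules, from 21.8 ± 1.92 to 2957 ± 54.0 CPM (SD, n = 3). Klf2, a transcription factor of quiescent T cells, fell from 584 ± 88.1 to 3.74 ± 0.52 CPM. Cd69, an early activation marker, was lower at 48 hours, at 77.6 ± 12.6 CPM against 361 ± 48.6. Among all 18374 genes tested 5880 rose and 6246 fell, and 3587 and 4268 of these changed by at least 2-fold.

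Among called genes with a mean log2 CPM of at least 3 over the 6 libraries compared and no overlap of the replicates, the 6 largest increases were those of Lif (log2 fold change 8.32 ± 0.12 SE, edgeR adjusted p = 2.4e-10), Gzmb (7.09 ± 0.12, adjusted p = 4.2e-10), Bcat1 (7.04 ± 0.20), Tg (6.63 ± 0.23), Tnfrsf8 (6.43 ± 0.27) and Egln3 (6.42 ± 0.13). The limit on the mean leaves out genes near 0 in one group, such as the cytokine Il24, which rose from 0 counts (floor of 0.0226 CPM) to 315 ± 59.7 CPM (adjusted p = 1.1e-07). Lif encodes a cytokine, Bcat1 an enzyme of branched-chain amino acid breakdown, Tnfrsf8 the receptor CD30 and Egln3 a prolyl hydroxylase that acts on hypoxia-inducible factors. By the same rule the 6 largest decreases were those of Igha (-10.16 ± 0.56), Lyz2 (-8.98 ± 0.65), Fosb (-8.37 ± 0.54), Igkc (-8.25 ± 0.45), Mpeg1 (-7.81 ± 0.34) and Klf2 (-7.28 ± 0.18, adjusted p = 2.6e-09). Igha and Igkc are immunoglobulin genes of B lineage cells, Lyz2 and Mpeg1 are expressed by myeloid cells, and Fosb is an immediate early gene. The proliferation marker Mki67 rose by 2.33 ± 0.65 (adjusted p = 0.0092), from 174 ± 178 to 873 ± 34.9 CPM. Its unstimulated level rested on library 2, without which the change was 3.61.

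Of the 29 T cell activation markers 21 rose and 7 fell (median log2 fold change 1.91, camera adjusted p = 3.7e-05, and adjusted p = 0.208 with an estimated correlation). Il2ra (6.06 ± 0.11, adjusted p = 6.0e-10) and Tnfrsf9, the costimulatory receptor 4-1BB (5.74 ± 0.14), led them, and Cd69 fell by 2.22 (adjusted p = 4.9e-07). Cytokines and cytotoxic effectors had 23 members higher and 5 lower of 32 (median 3.50, or 2.01 among genes of at least 10 CPM; adjusted p = 6.1e-05, and adjusted p = 0.253 with an estimated correlation). Ccl5, a chemokine of memory CD8 and NK cells, went from 88.2 ± 8.08 to 3.32 ± 0.49 CPM, with a log2 change of -4.73. NF-kB target genes were mixed, with 17 higher and 8 lower of 30 (median 0.46, adjusted p = 0.0434, and adjusted p = 0.397 with an estimated correlation). Lta rose by 5.22 ± 0.13 and Nfkb1, the p105 subunit, by 1.46 ± 0.07, whereas Nfkbiz fell by 1.93. Nfkbia, which encodes the inhibitor IkB-alpha, was at 166 ± 20.7 and 153 ± 5.55 CPM (log2 fold change -0.12, adjusted p = 0.390). Nfkbia was called as lower under upper-quartile scaling (-0.34, adjusted p = 0.0208) and among genes of at least 10 CPM (-0.28, adjusted p = 0.0314). The call of the NF-kB list was lost under 5 of 17 alternatives, with a median of 0.16 and adjusted p = 0.293 among genes of at least 10 CPM, 0.23 and 0.0558 under upper-quartile scaling, and without unstimulated library 2 (0.43, adjusted p = 0.0660). The counts adjusted over the list alone were equal for these lists except for cytokines, with 6 members lower.

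All 23 glycolysis genes were higher (median 2.75, camera adjusted p = 2.8e-11, and adjusted p = 0.109 with an estimated correlation), among them Aldoa (198 ± 4.08 to 1953 ± 51.0 CPM) and Gapdh (214 ± 18.8 to 2484 ± 116 CPM). All 24 tested cholesterol synthesis genes rose (median 2.37, adjusted p = 2.8e-11, and adjusted p = 0.189 with an estimated correlation), including Stard4 (2.94 ± 0.09) and Hmgcs1 (2.43 ± 0.08). So did all 30 ribosome biogenesis genes (median 1.37, adjusted p = 6.1e-11, and adjusted p = 0.268 with an estimated correlation), including Npm1 (2.18 ± 0.10) and Rrp1b (1.63 ± 0.07). All 31 nuclear oxidative phosphorylation genes were higher (median 1.33, adjusted p = 6.8e-09, and adjusted p = 0.385 with an estimated correlation), with the ATP synthase genes Atp5b at 2.02 ± 0.12 and Atp5a1 at 1.53 ± 0.09. Of 30 targets of ATF4, 27 rose and 1 fell (median 3.01, adjusted p = 9.8e-11, and adjusted p = 0.208 with an estimated correlation). The serine synthesis genes Psat1 (22.7 ± 3.73 to 507 ± 23.0 CPM) and Phgdh (24.3 ± 0.43 to 261 ± 0.83 CPM) were among those that rose, and Cebpb fell by 1.16. Unfolded protein response genes had 16 members higher and 5 lower of 22 (median 0.65, adjusted p = 0.0129, and adjusted p = 0.429 with an estimated correlation), with Hyou1 at 1.30 ± 0.08, Manf at 1.64 ± 0.11 and Dnajb9 at -3.08 ± 0.19. This call was lost among genes of at least 10 CPM (adjusted p = 0.0981). The median was 0.43 under upper-quartile scaling. For these lists the counts adjusted over the list alone were equal except for 28 ATF4 targets higher.

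Of 34 cell cycle genes 31 rose and 0 fell (median 2.42, camera adjusted p = 3.1e-08, and adjusted p = 0.397 with an estimated correlation), and 32 rose adjusted over the list alone. The replication licensing gene Mcm4 went from 101 ± 19.3 to 323 ± 7.18 CPM and Gins2, of the replicative helicase, from 3.25 ± 1.54 to 34.5 ± 2.23 CPM. Replication-dependent histone genes had 19 of 20 members higher (19 adjusted over the list alone; median 2.73, adjusted p = 4.7e-05, and adjusted p = 0.440 with an estimated correlation), such as Hist1h4d (2.69 ± 0.36) and Hist1h3e (3.24 ± 0.45). Histone genes have near-identical copies, so the share of each is uncertain. Unstimulated library 2 had the highest levels of its group for Mki67 and Plk1 and also for the myeloid genes Lyz2, Mpeg1 and Csf1r, and without it the cell cycle median was 3.25. Mitochondrially encoded genes had 3 of 12 members higher (2 adjusted over the list alone; median 0.52, adjusted p = 0.135), and the list was called only without unstimulated library 1 (adjusted p = 0.0382). Its median was 0.21 without stimulated library 2, 0.31 under upper-quartile scaling and 0.04 among genes of at least 10 CPM. For p53 and apoptosis genes, 14 rose and 8 fell of 26, also when adjusted over the list alone (median 0.71, adjusted p = 0.265).

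Naive and quiescence genes fell, with 26 of 31 lower and 4 higher (median -1.87, camera adjusted p = 1.8e-06, and adjusted p = 0.346 with an estimated correlation). Klf3 decreased from 553 ± 37.8 to 11.4 ± 1.90 CPM, and Bcl2, a survival gene, rose by 0.86 ± 0.09. Interferon-stimulated genes were lower in 21 and higher in 8 of 33 (median -0.92, adjusted p = 0.0363, and adjusted p = 0.440 with an estimated correlation), with Ddx58 (-2.28 ± 0.12) and Irf7 (-2.57 ± 0.19) lower and Socs1, a feedback inhibitor of cytokine receptors, higher (2.41 ± 0.25). The interferon call was lost under 5 of 17 alternatives, with adjusted p = 0.184 among genes of at least 10 CPM, 0.0531 without unstimulated library 1 and 0.0513 without stimulated library 3. CD8 lineage genes were lower in 9 and higher in 2 of 11 (median -1.36, adjusted p = 0.0179, and adjusted p = 0.372 with an estimated correlation). Besides Ccl5, Ctsw fell by 1.94 and Runx3 rose by 0.83. These 3 lists had equal counts adjusted over the list alone.

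Markers of other cells fell with the same contrast. B cell markers were lower in 16 of 17 (median -4.08, camera adjusted p = 9.5e-06, and adjusted p = 0.397 with an estimated correlation), with Ighm going from 625 ± 248 to 55.7 ± 4.52 CPM. Myeloid and dendritic cell markers were lower in 25 of 26 (median -9.35, or -7.86 with 8 members that had 0 counts in a group set at their bound; adjusted p = 6.4e-10, and adjusted p = 0.208 with an estimated correlation), and Csf1r went from 126 ± 27.7 to 0.284 ± 0.106 CPM. NK cell markers were lower in 11 of 12 (median -3.14, adjusted p = 6.1e-05, and adjusted p = 0.109 with an estimated correlation), with Ncr1 at 74.1 ± 4.41 and 1.46 ± 0.33 CPM and Klrb1c at -4.33 ± 0.28. Erythroid and platelet markers were lower in 10 of 13 (median -6.57, adjusted p = 0.0086, and adjusted p = 0.440 with an estimated correlation). Their unstimulated levels varied, with Car1 at 44.8 ± 41.7 and Alas2 at 98.6 ± 103 CPM, and the call of Alas2 was lost with limma voom (adjusted p = 0.179). The counts adjusted over the list alone were equal for all 4 lists. Immunoglobulin genes took 0.541 ± 0.247% of the counts in unstimulated and 0.007% in each stimulated library. The fall of these markers accompanied that of the naive, CD8 lineage, interferon-stimulated and X-linked immune genes.

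Within the T cell makeup, regulatory T cell genes moved both ways, with 9 higher and 7 lower of 17 (8 lower adjusted over the list alone; median 1.60, camera adjusted p = 0.243). Foxp3, the lineage factor, fell from 22.9 ± 4.11 to 2.05 ± 0.24 CPM, and Ctla4 rose from 8.56 ± 1.17 to 148 ± 16.1 CPM. CD4 lineage genes had 2 members higher and 4 lower of 6, equally so adjusted over the list alone; their median was -0.57, their mean 0.29 and the direction of the test downward (adjusted p = 0.742). Cd4 itself went from 274 ± 52.9 to 184 ± 2.58 CPM, with a log2 change of -0.57.

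Culture for 48 hours and stimulation coincided in this comparison, so its changes cannot be assigned to either alone. Unstimulated cells were taken straight after enrichment on columns, so any effect of that handling on their levels is part of the comparison too. Upper-quartile scaling moved the median change of all genes from -0.05 to -0.27, and changes of this size in single genes depend on the scaling.

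**Figure D1:**
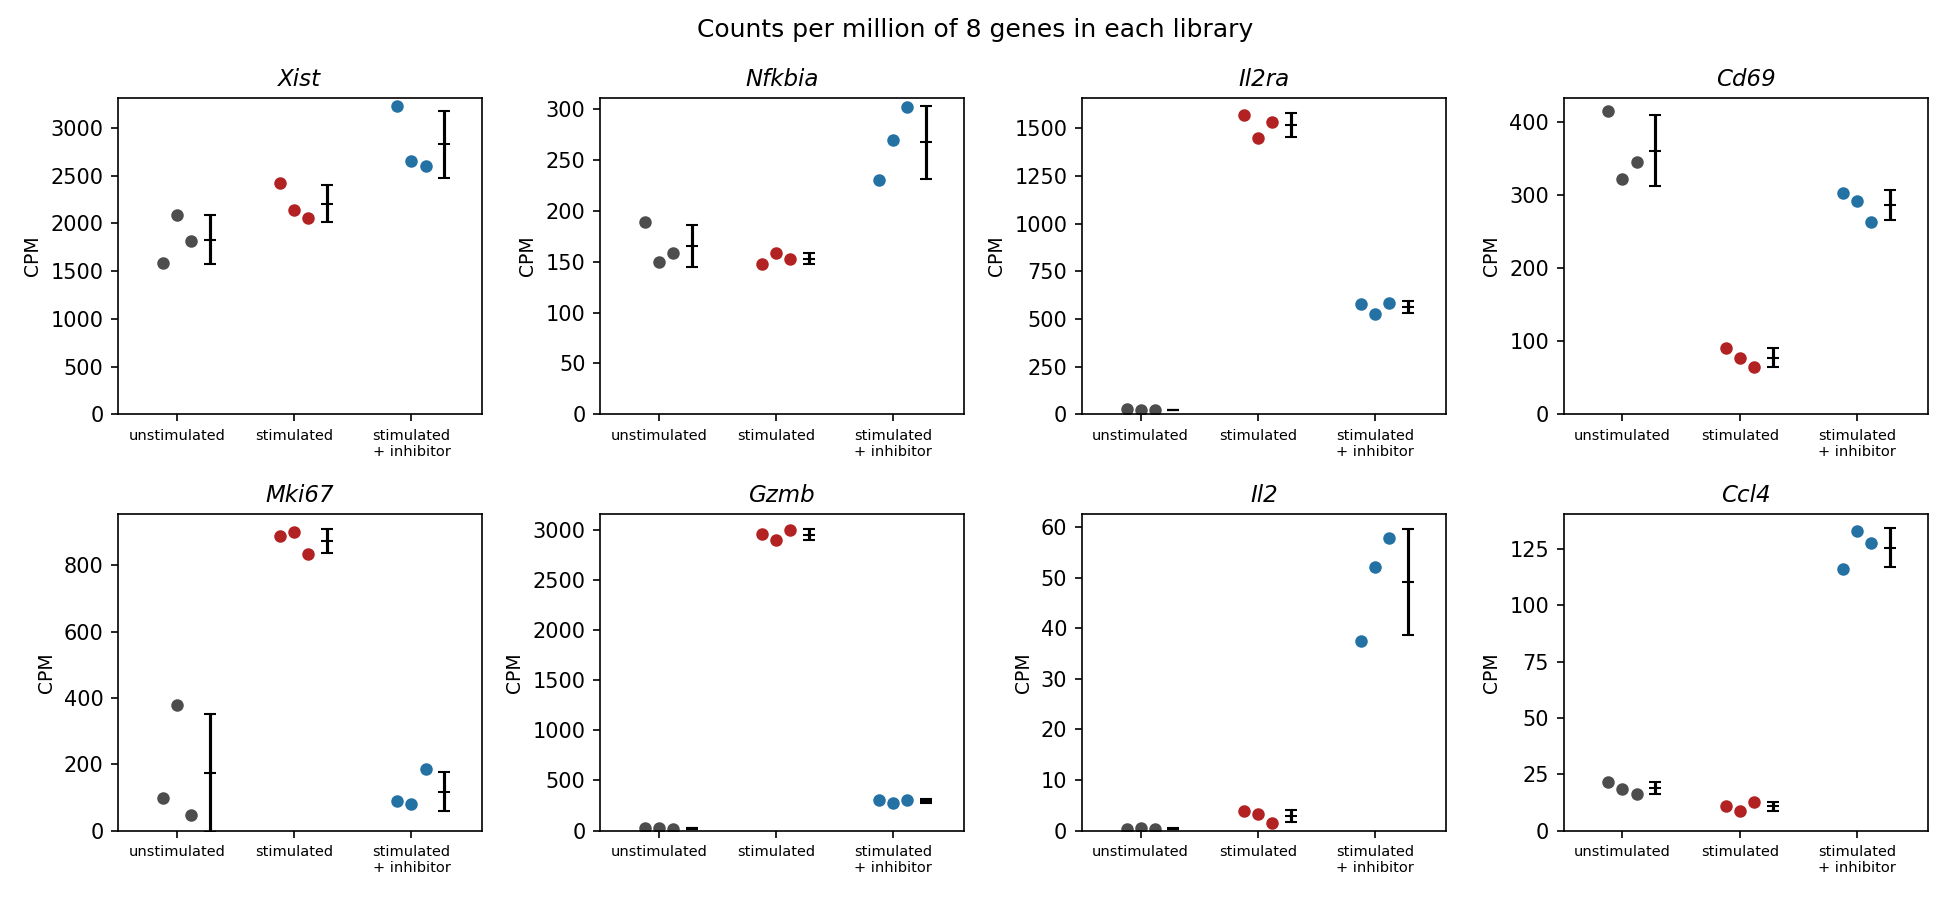
CPM (linear axes from 0) of 8 genes in each of the 9 libraries, 1 point per library, with the mean and SD (n = 3) beside each group; the lower SD bar of unstimulated Mki67 is clipped at 0. Il2ra and Gzmb stood highest in stimulated libraries (means 1518 and 2957 CPM), whereas Nfkbia, Il2 and Ccl4 stood highest with the inhibitor (267, 49.1 and 126 CPM).

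The second comparison asked what the IKK-beta inhibitor changed in cells stimulated for the same time. Gzmb decreased from 2957 ± 54.0 to 294 ± 18.3 CPM, Il2ra from 1518 ± 62.9 to 564 ± 31.4 and Mki67 from 873 ± 34.9 to 117 ± 58.7 CPM (SD, n = 3). Most NF-kB target genes called in this comparison were higher with the inhibitor, Nfkbia among them (153 ± 5.55 to 267 ± 35.9 CPM; log2 fold change 0.81 ± 0.12, edgeR adjusted p = 3.7e-04). Cd69 rose from 77.6 ± 12.6 to 286 ± 20.5 CPM. In total 3990 genes rose and 4192 fell, of which 1711 and 1989 changed by at least 2-fold.

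Among called genes with a mean log2 CPM of at least 3 over these 6 libraries whose replicates did not overlap, the 6 largest increases were those of the chemokine Ccl3 (4.19 ± 0.35, adjusted p = 1.2e-05), the T cell growth factor Il2 (4.09 ± 0.34, adjusted p = 1.3e-05), the chemokine Xcl1 (3.91 ± 0.23), the receptor gene Slamf6 (3.59 ± 0.22), the chemokine Ccl4 (3.55 ± 0.16) and Mndal, of the interferon-inducible p200 family (3.53 ± 0.27). Il2 was at 0.323 ± 0.109 CPM in unstimulated, 2.89 ± 1.26 in stimulated and 49.1 ± 10.4 in inhibitor-treated cells. The 6 largest decreases by that rule were those of the cytokine Il24 (-9.40 ± 0.33, adjusted p = 9.1e-07), the granzyme Gzma (-7.39 ± 0.37), the transglutaminase Tgm2 (-7.30 ± 0.39), Tnfrsf8 (-6.69 ± 0.28), the mitochondrial protein gene Bnip3 (-6.27 ± 0.27) and Egln3 (-6.27 ± 0.13, adjusted p = 6.3e-09). Il24 was at 315 ± 59.7 CPM in stimulated and 0.469 ± 0.237 in inhibitor-treated cells, with 0 counts in unstimulated cells (floor of 0.0226 CPM).

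Of 30 NF-kB target genes, 17 rose, 4 fell and 9 were not called (median 0.59, camera adjusted p = 5.7e-04, and adjusted p = 0.230 with an estimated correlation), and 18 rose and 5 fell adjusted over the list alone. Besides Ccl3 and Ccl4, Irf1 (1.93 ± 0.13), a transcription factor of the interferon response, Tnf (54.2 ± 4.45 to 132 ± 9.85 CPM) and Nfkb2 (310 ± 33.8 to 493 ± 41.3 CPM) rose. The mitochondrial superoxide dismutase gene Sod2 fell by 0.90, and Bcl3, Lta and Nfkb1 fell by 1.60, 0.38 and 0.28. Tnf, Nfkb2, Bcl3 and the falls of Lta and Nfkb1 were picked out after their values were seen. Myeloid and dendritic cell markers rose with the list, in 8 of 26 members and in 8 adjusted over the list alone (median 2.48, or 1.67 with 8 members at their bound and 1.53 among genes of at least 10 CPM; adjusted p = 0.0024, and adjusted p = 0.397 with an estimated correlation). Ctss was at 53.3 ± 1.20 CPM with the inhibitor, 23.3 ± 2.33 in stimulated and 140 ± 22.8 in unstimulated cells, and Mpeg1 at 10.3 ± 3.91, 1.88 ± 0.30 and 421 ± 104 CPM. Of 17 B cell markers 9 rose and 0 fell, without a call of the list (1.07, adjusted p = 0.0586). Ighm went from 55.7 ± 4.52 to 121 ± 1.85 CPM. Mitochondrially encoded genes were higher in 6 of 12 (7 adjusted over the list alone; median 0.96, adjusted p = 0.0054, and adjusted p = 0.397 with an estimated correlation), such as mt-Co1 (9674 ± 650 to 15830 ± 2145 CPM) and mt-Nd1 (1094 ± 275 to 2392 ± 359 CPM). The members mt-Atp6, mt-Co2, mt-Co3, mt-Nd3 and mt-Nd4l had under 2.5 CPM in both groups and have nuclear copies, so their values are uncertain. Mitochondrial protein-coding genes took 1.40 ± 0.121% of the counts of stimulated and 2.58 ± 0.264% of those of inhibitor libraries.

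All 23 glycolysis genes fell (median -2.22, camera adjusted p = 1.5e-15, and adjusted p = 0.109 with an estimated correlation), for example Pkm, from 2473 ± 161 to 343 ± 24.3 CPM, and the lactate transporter Slc16a3, from 238 ± 7.71 to 9.26 ± 0.02 CPM. Cholesterol synthesis genes fell in 23 of 24 (median -0.70, adjusted p = 1.3e-08, and adjusted p = 0.208 with an estimated correlation), including Stard4 (-1.70 ± 0.09) and Lss (-1.60 ± 0.09). Nuclear oxidative phosphorylation genes were lower in 28 of 31 (29 adjusted over the list alone; median -0.72, adjusted p = 1.1e-08, and adjusted p = 0.386 with an estimated correlation), with Uqcrc1 at -1.23 ± 0.09 and Atp5a1 at -0.95 ± 0.09. Among 30 ATF4 targets 18 fell and 1 rose (median -0.62, adjusted p = 0.0010, and adjusted p = 0.397 with an estimated correlation). Ddit4, an inhibitor of mTORC1 signalling, fell by 3.03 and Psph by 1.52, whereas Atf5 rose from 30.5 ± 0.55 to 108 ± 7.07 CPM. Ribosome biogenesis genes were lower in 14 and higher in 3 of 30 (15 lower adjusted over the list alone; median -0.28, adjusted p = 0.0091, and adjusted p = 0.564 with an estimated correlation), with Rrp1b at -0.52 ± 0.07, Nhp2 at -0.98 ± 0.15 and Tsr1 at 0.50 ± 0.11. This call was lost without inhibitor library 1, the library with counts in many more genes (median -0.18, adjusted p = 0.0653). Its median was -0.16 under upper-quartile scaling. The glycolysis, cholesterol and ATF4 lists had equal counts adjusted over the list alone.

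Cell cycle genes fell in 31 and rose in 1 of 34 (32 lower adjusted over the list alone; median -1.71, camera adjusted p = 1.4e-08, and adjusted p = 0.397 with an estimated correlation). The mitotic kinase gene Plk1 went from 133 ± 6.91 to 6.06 ± 1.61 CPM and the cyclin gene Ccnd3 fell by 0.96, while another cyclin gene, Ccnd2, rose from 722 ± 84.5 to 1334 ± 7.46 CPM. All 20 histone genes fell, also when adjusted over the list alone (median -2.67, adjusted p = 2.1e-07, and adjusted p = 0.397 with an estimated correlation), with Hist1h3d at -4.69 ± 0.60 and Hist1h3e at -2.91 ± 0.45. Cytokines and cytotoxic effectors were lower in 16 and higher in 8 of 32, equally so adjusted over the list alone (median -1.19, or -1.06 with 2 members at their bound; adjusted p = 0.0171, and adjusted p = 0.397 with an estimated correlation). Gzmb and Lif fell by 3.33 and 2.04, opposite to Il2, Ccl3 and Ccl4. The call of this list was lost among genes of at least 10 CPM (median -0.34, adjusted p = 0.374) and with 2 libraries per group (adjusted p = 0.0538). NK cell markers fell in 10 and rose in 1 of 12, also adjusted over the list alone (median -2.10, adjusted p = 5.6e-05, and adjusted p = 0.109 with an estimated correlation). Gzma and Klra4 (-4.99 ± 0.34) were lower, and Eomes, a T-box factor, was higher (1.08 ± 0.16). Klra genes form a family of near-identical copies, so their single values are uncertain.

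The other 13 lists were not called. T cell activation markers had 8 members higher and 13 lower of 29 (9 and 14 adjusted over the list alone; median -0.16, camera adjusted p = 0.140), naive genes 14 higher and 11 lower of 31 (14 and 11; 0.25, adjusted p = 0.311) and unfolded protein response genes 10 higher and 10 lower of 22 (10 and 10; -0.15, adjusted p = 0.947). Interferon-stimulated genes had 10 higher and 16 lower of 33 (11 and 16; -0.51, adjusted p = 0.188) and p53 genes 7 higher and 10 lower of 26 (8 and 11; -0.29, adjusted p = 0.365). Regulatory T cell genes had 3 higher and 8 lower of 17 (4 and 8; -0.86, adjusted p = 0.0594; called under 3 of 17 alternatives), and Foxp3 rose to 7.18 ± 0.83 CPM while Ctla4 fell to 10.3 ± 1.36. CD4 lineage genes had 4 higher and 2 lower of 6 (4 and 2; 0.68, adjusted p = 0.410), CD8 lineage genes 3 higher and 4 lower of 11 (3 and 5; -0.32, adjusted p = 0.453), and B cell markers 9 higher and 0 lower of 17 (9 and 1; 1.07, adjusted p = 0.0586; called under 4 of 17 alternatives). Erythroid and platelet markers had 0 higher and 1 lower of 13 (0 and 0); their median was 0.67 and mean 0.41, but the test pointed downward (adjusted p = 0.985).

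The labels name no vehicle in the stimulated cultures, so the comparison includes any effect of the solvent. Upper-quartile scaling moved the median change of all genes from 0.03 to 0.16.

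**Figure D2:**
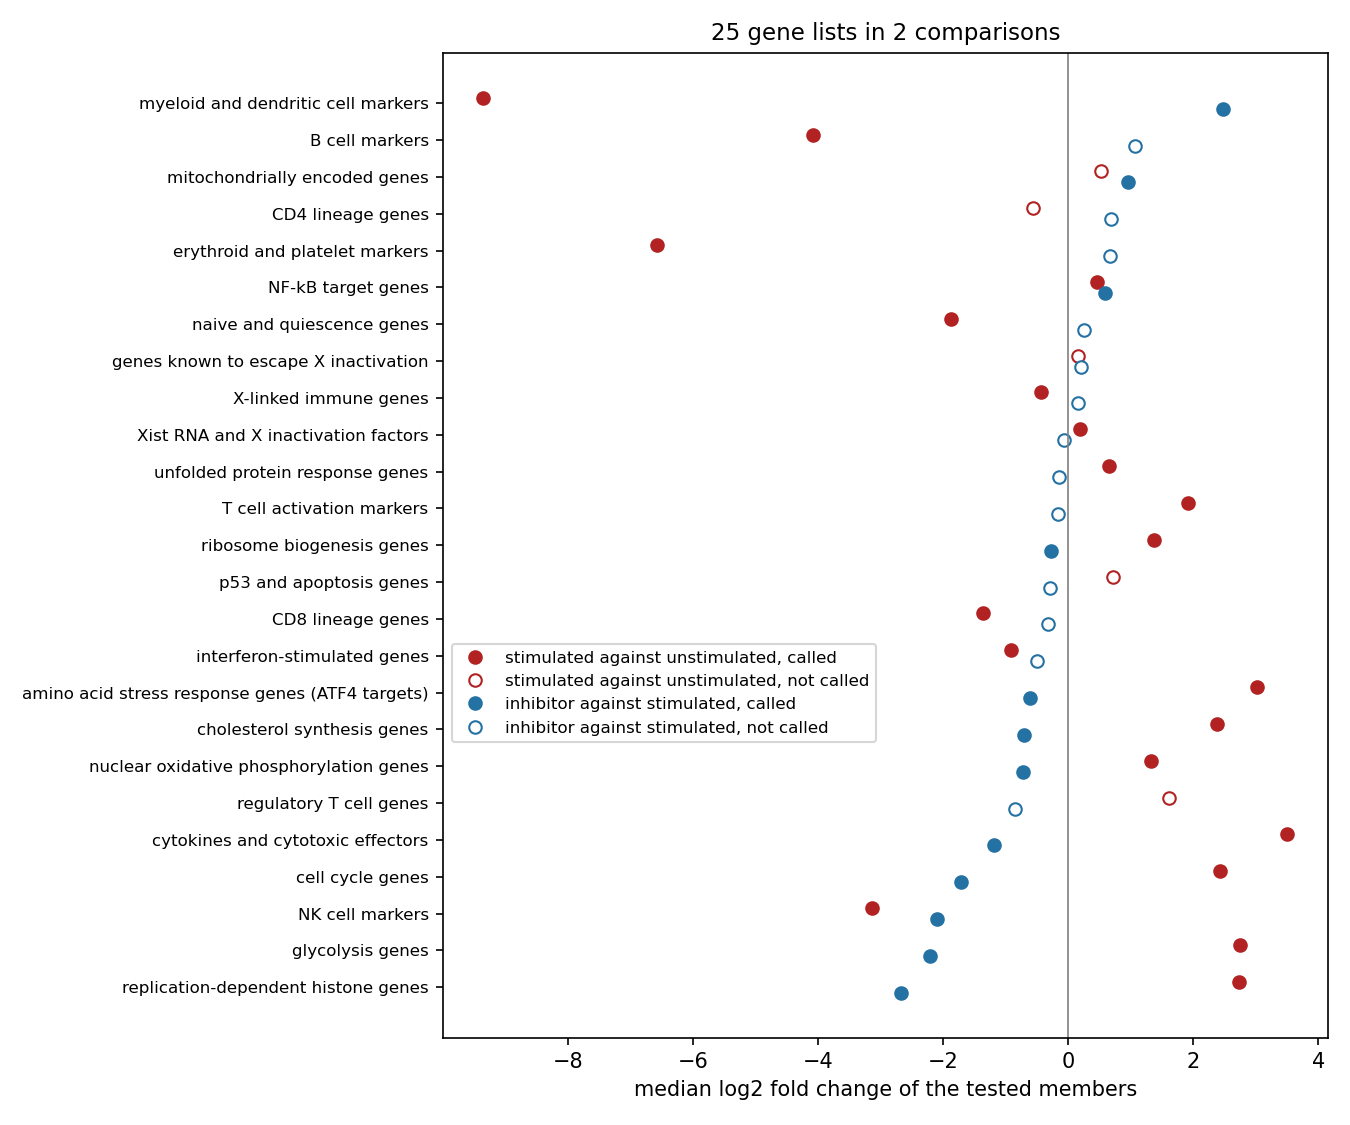
Median log2 fold change of the tested members of 25 gene lists, for stimulated against unstimulated cells and for the inhibitor against stimulated cells; filled points passed the camera test with the preset correlation and open points did not. Glycolysis genes lay at 2.75 and -2.22, and NF-kB target genes at 0.46 and 0.59.

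Many genes that stimulation changed moved the other way with the inhibitor. Egln3 went from 3.24 ± 0.43 to 278 ± 16.7 and then 3.61 ± 0.32 CPM, and Tnfrsf8 from 1.81 ± 0.51 to 155 ± 23.0 and 1.49 ± 0.46 CPM (unstimulated, stimulated, inhibitor; SD, n = 3). Of the 5880 genes that rose with stimulation 3141 (53.4%) fell with the inhibitor, where 1342 would be shared by independent sets of these sizes, and 346 rose again. Of the 6246 that fell 2806 (44.9%) rose with the inhibitor, against 1356 for independent sets, and 392 fell again. Against unstimulated cells, 1559 of the 3141 were still higher, 1352 were not called and 230 were lower. For the 2806, 1233 were still lower, 1343 not called and 230 higher. Both comparisons use the stimulated libraries, and in 20 simulated data sets with no effect 80.4% (median; at most 81.7%) of the 5000 genes ranked first for stimulation had opposite signs, against 86.4% in the data. The first 5000 genes held only noise in the simulated sets but were called genes in the data, so these shares are not on the same scale. In the simulated sets at most 1 gene was called higher and then lower, and at most 0 lower and then higher, against 3141 and 2806. With no effect simulated few genes can be called at all, so this low overlap was set in advance. It cannot show how much of the overlap in the data comes from the shared libraries. The 3 stimulated libraries are too few to split, so the overlap includes what they share.

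**Figure D3:**
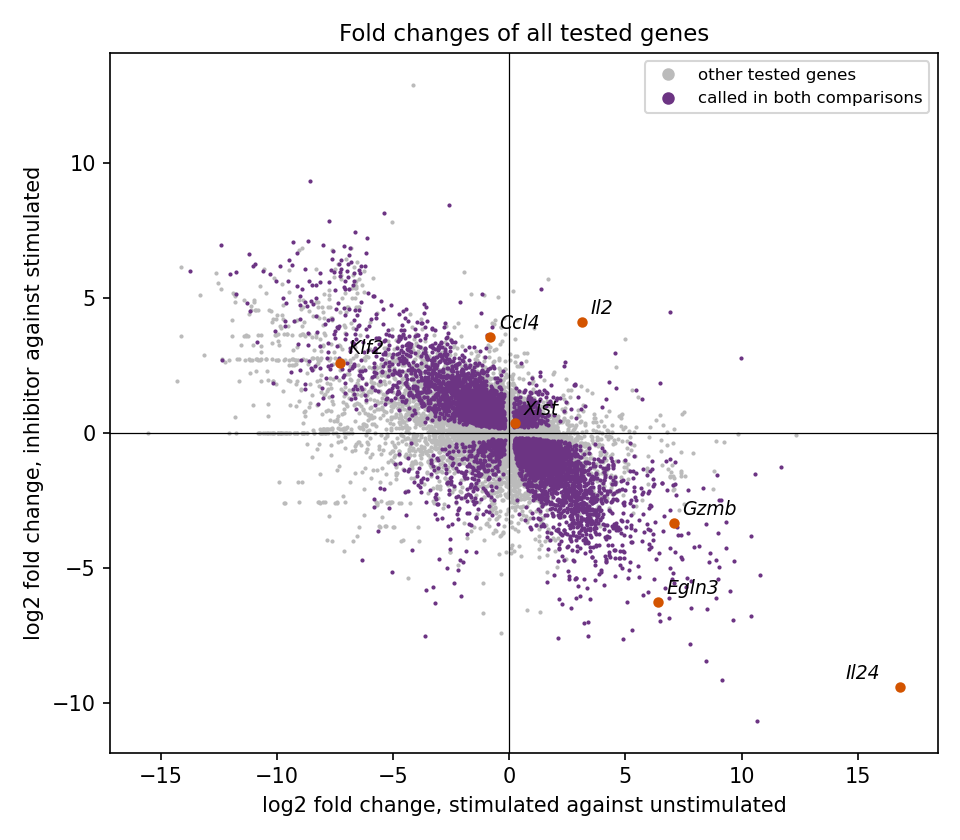
Log2 fold changes of all 18374 tested genes, for stimulated against unstimulated cells (horizontal) and inhibitor against stimulated cells (vertical), with genes called in both comparisons in purple and 7 named genes in orange. Both axes share the stimulated libraries, which alone tilts the points downward, and the positions of genes with 0 counts in a group, such as Il24, depend on the prior count.

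The third comparison set inhibitor-treated stimulated cells against unstimulated ones. Il2ra was at 564 ± 31.4 against 22.7 ± 2.23 CPM (log2 fold change 4.64 ± 0.11, edgeR adjusted p = 6.0e-09) and Nfkbia at 267 ± 35.9 against 166 ± 20.7 (0.69 ± 0.12, adjusted p = 6.3e-04). Cd69 (-0.34, adjusted p = 0.0539) and Mki67 (-0.57, adjusted p = 0.474) were not called. Cd69 was called, as lower, under 13 of 20 alternatives (-0.47 to -0.23, adjusted p = 0.0064 to 0.198). Mki67 was called under 1 of 20, without a count filter (adjusted p = 0.0293), and its change was 0.71 without unstimulated library 2. Of all genes 4826 were higher and 4800 lower.

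In this comparison NF-kB target genes were higher in 22 and lower in 3 of 30 (median 0.86, camera adjusted p = 4.6e-06, and adjusted p = 0.189 with an estimated correlation). Activation markers were higher in 20 and lower in 3 of 29 (1.04, adjusted p = 2.6e-06, and adjusted p = 0.189 with an estimated correlation). Cytokines were higher in 21 and lower in 8 of 32 (3.28, adjusted p = 5.3e-04, and adjusted p = 0.329 with an estimated correlation). ATF4 targets were higher in 25 and lower in 2 of 30 (2.46, adjusted p = 6.0e-10, and adjusted p = 0.226 with an estimated correlation). All 30 ribosome biogenesis genes were higher (1.15, adjusted p = 1.7e-11, and adjusted p = 0.253 with an estimated correlation), with 23 of 24 cholesterol synthesis genes (1.18, adjusted p = 2.2e-10, and adjusted p = 0.189 with an estimated correlation) and 18 of 31 nuclear oxidative phosphorylation genes (0.52, adjusted p = 1.6e-04, and adjusted p = 0.479 with an estimated correlation). Mitochondrially encoded genes were higher in 10 of 12 (1.37, adjusted p = 4.2e-04, and adjusted p = 0.332 with an estimated correlation) and unfolded protein response genes higher in 16 and lower in 4 of 22 (0.64, adjusted p = 0.0024, and adjusted p = 0.397 with an estimated correlation). Glycolysis genes were higher in 14 and lower in 5 of 23 (0.64, adjusted p = 0.0129, and adjusted p = 0.395 with an estimated correlation), and cell cycle genes higher in 15 and lower in 4 of 34 (0.64, adjusted p = 0.0129, and adjusted p = 0.660 with an estimated correlation). Both calls were lost among genes of at least 10 CPM (medians 0.50 and 0.51 for cell cycle and glycolysis, adjusted p = 0.0683 for each). The cell cycle median was 1.36 without unstimulated library 2, 0.34 (adjusted p = 0.0930) without unstimulated library 3 and 0.36 without inhibitor library 3. Adjusted over the list alone, the counts of these lists differed for activation markers (21 and 4), cytokines (22 higher), oxidative phosphorylation (19), mitochondrial (11) and glycolysis genes (15 higher).

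Naive genes were lower in 25 and higher in 3 of 31 (median -1.38, camera adjusted p = 4.9e-08, and adjusted p = 0.292 with an estimated correlation). Interferon-stimulated genes were lower in 24 and higher in 7 of 33 (-1.55, adjusted p = 6.0e-04, and adjusted p = 0.332 with an estimated correlation). CD8 lineage genes were lower in 9 of 11 (-1.20, adjusted p = 2.8e-04, and adjusted p = 0.208 with an estimated correlation). The markers of other cells were lower too: 15 of 17 for B cells (-3.42, adjusted p = 2.8e-06, and adjusted p = 0.397 with an estimated correlation), 25 of 26 for myeloid cells (-6.01, adjusted p = 2.8e-11, and adjusted p = 0.192 with an estimated correlation), 12 of 12 for NK cells (-5.67, adjusted p = 1.2e-08, and adjusted p = 0.0839 with an estimated correlation) and 10 of 13 for erythroid cells and platelets (-6.75, adjusted p = 0.0019, and adjusted p = 0.397 with an estimated correlation). Histone genes (0 higher and 1 lower of 20, median -0.01 with the test upward, adjusted p = 0.925, and 1.10 with 2 libraries per group, adjusted p = 0.0113), p53 genes (11 and 8 of 26; 0.23, adjusted p = 0.448), regulatory T cell genes (8 and 5 of 17; 0.26, adjusted p = 0.195) and CD4 lineage genes (2 and 2 of 6; 0.11, adjusted p = 0.448) were not called. The median of the erythroid and platelet markers ran from -7.56 to -4.62 without single libraries. Adjusted over the list alone, the counts differed for naive genes (26 lower) and interferon-stimulated genes (8 higher).

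Xist, the long noncoding RNA that coats the inactive X chromosome, was measured at 1830 ± 252 CPM in unstimulated, 2206 ± 192 in stimulated and 2828 ± 350 in inhibitor-treated cells (ENSMUSG00000086503, chromosome X, 103460366 to 103483254 on the minus strand, mm10; SD, n = 3). The change with stimulation was not called (log2 fold change 0.27 ± 0.13, edgeR adjusted p = 0.0968; 3 of 20 alternatives called it). The libraries of these groups overlapped. The change was 0.05 (adjusted p = 0.777) under upper-quartile scaling, 0.10 (0.552) among genes of at least 10 CPM and 0.18 (0.268) without unstimulated library 1. With the inhibitor Xist was higher than in stimulated cells, by an amount at the edge of the test (0.36 ± 0.13, adjusted p = 0.0499), and all 3 inhibitor libraries lay above the 3 stimulated ones. This call was lost under 7 of 20 alternatives, including without inhibitor library 1 (0.25, adjusted p = 0.162), inhibitor library 2 (adjusted p = 0.0712), stimulated library 2 (0.147) or 3 (0.156) and unstimulated library 3 (0.0539), and with DESeq2 size factors (0.0572). The remaining loss was with the replicate number as a block. Against unstimulated cells Xist rose by 0.63 ± 0.13 (adjusted p = 0.0027), under 20 of 20 alternatives. Tsix, its antisense partner, had 2.61 ± 0.89, 2.10 ± 0.27 and 2.22 ± 0.58 CPM and was not called.

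Among 37 genes of Xist RNA and X inactivation factors, 17 rose and 8 fell with stimulation, the same numbers as adjusted over the list alone (median 0.19, camera adjusted p = 0.0417, and adjusted p = 0.208 with an estimated correlation). Pcgf5, a Polycomb component, went from 18.6 ± 1.35 to 88.8 ± 5.49 CPM, Ptbp1, a splicing regulator, rose by 1.09 ± 0.08, and Ythdc1, a reader of methylated adenosine in RNA, fell by 1.00. This call was lost under 5 of 17 alternatives, with adjusted p = 0.382 among genes of at least 10 CPM and a median of -0.04 under upper-quartile scaling. With the inhibitor 8 rose and 11 fell (9 and 13 adjusted over the list alone; median -0.07, adjusted p = 0.525). Dnmt1, the maintenance DNA methyltransferase, fell from 601 ± 45.6 to 275 ± 43.8 CPM, Lbr, a nuclear envelope receptor that binds Xist RNA, from 317 ± 14.5 to 153 ± 11.4, and Smchd1, a chromatin protein of the inactive X, from 376 ± 1.78 to 254 ± 7.82. Spen, a silencing factor bound by Xist, rose from 181 ± 12.4 to 281 ± 8.29 CPM and Ring1, a Polycomb ubiquitin ligase, from 17.3 ± 1.92 to 35.2 ± 2.17. These 5 factors were picked out after their values were seen. Against unstimulated cells 17 factors were higher and 4 lower with the inhibitor (19 and 4 adjusted over the list alone; median 0.30, adjusted p = 0.0114, and adjusted p = 0.189 with an estimated correlation), a call lost among genes of at least 10 CPM (median 0.18, adjusted p = 0.184).

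Genes known to escape X inactivation were not called as a list, with 6 higher and 4 lower of 15 for stimulation (median 0.16, camera adjusted p = 0.369), 5 and 2 for the inhibitor (0.21, adjusted p = 0.525) and 7 and 2 for the inhibitor against unstimulated cells (0.35, adjusted p = 0.0682), the same counts as adjusted over the list alone. Uba1 went from 286 ± 13.7 to 766 ± 22.0 and 403 ± 8.27 CPM, while Kdm6a was at 183 ± 8.77, 131 ± 1.02 and 143 ± 4.86 CPM. X-linked immune genes were lower in 16 and higher in 6 of 32 with stimulation (median -0.44, adjusted p = 0.0405, and adjusted p = 0.230 with an estimated correlation). The chemokine receptor gene Cxcr3 went from 33.1 ± 3.38 to 3.64 ± 0.33 CPM, Foxp3 fell by 3.48 and the kinase gene Pim2 rose by 2.50. Btk, Cybb, Tlr7 and Tlr8 of this list are expressed mainly by B and myeloid cells, whose markers fell in the same comparison. The call was lost without unstimulated library 3 (adjusted p = 0.0672), stimulated library 3 (0.0531) or inhibitor library 1 (0.0589). The list median was -0.66 under upper-quartile scaling. With the inhibitor 13 of these genes rose and 6 fell (median 0.16, adjusted p = 0.220), and against unstimulated cells 5 were higher and 18 lower (median -0.52, adjusted p = 0.0275, and adjusted p = 0.208 with an estimated correlation). Adjusted over the list alone, the counts of X-linked immune genes were equal in all 3 comparisons.

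X-linked genes as a group were not called against all other genes tested. Medians of the 587 X-linked and 17705 autosomal genes differed by 0.22 for stimulation (camera adjusted p = 0.371), -0.02 for the inhibitor (adjusted p = 0.862) and 0.12 for the inhibitor against unstimulated cells (adjusted p = 0.371). Among genes of at least 10 CPM the differences were -0.02, 0.09 and 0.02 (adjusted p = 0.940 in each). Single autosomes had medians from -0.43 (chromosome 6) to 0.17 (chromosome 15) for stimulation, and the X-linked median was 0.17. Of the X-linked genes 191 rose and 156 fell with stimulation, and 121 rose and 119 fell with the inhibitor. Summed over the chromosome without Xist, X-linked counts were 23428 to 24233 CPM in unstimulated, 26004 to 27748 in stimulated and 23065 to 24212 in inhibitor libraries. Gene-level counts sum both alleles and cannot show which X chromosome a transcript came from.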

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

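The settings with 2 libraries per group and without rRNA-like genes and Rpph1 were chosen after the data had been seen. Of 22 alternatives, 20 applied to genes and 17 to lists. Of the values of named genes 2824 kept their direction and side of the threshold, 19 came to pass it, 8 no longer did and 6 reversed. For lists the numbers were 1308, 10, 83 and 21, and 3 values of X-linked against autosomal genes reversed. None of these 30 values, nor the result it reversed, was called. For lists the direction is that of camera, which can differ from the sign of the median. With at least 10 CPM in 3 libraries, which tests fewer genes, stimulation called 3738 higher and 3763 lower, and the inhibitor against unstimulated cells 3173 and 3148. With a minimum fold of 2, which asks for more by construction, stimulation called 3587 higher, the inhibitor 1711 higher and 1989 lower, and the inhibitor against unstimulated cells 1981 and 3150. The genes that moved back were then 1320 (higher with stimulation) and 1206 (lower with stimulation). With an estimated correlation, camera called 0 lists higher and 0 lower for stimulation, 0 and 0 for the inhibitor, and 0 and 0 for the inhibitor against unstimulated cells, where 7, 3 and 8 lists had an unadjusted p under the threshold.

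Leaving out each library in turn gave 5363 to 6076 genes higher and 5662 to 6619 lower for stimulation, 3116 to 4064 and 3424 to 4419 for the inhibitor, and 4103 to 4797 and 4181 to 5154 for the inhibitor against unstimulated cells. Genes that moved back then numbered 2567 to 3291 and 2211 to 2784, and lists called 11 to 13 higher and 6 to 8 lower, 3 to 4 and 8 to 10, and 11 to 13 and 8. Under upper-quartile scaling the share of calls that were higher went from 48.5% to 39.7% for stimulation and from 48.8% to 58.6% for the inhibitor.

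For Mki67 with the inhibitor against unstimulated cells, -0.57 became 0.863 with 2 libraries per group and ran from -1.055 to 0.708 without single libraries. Trac with stimulation (-0.01) was at 0.008 with limma voom and -0.147 to 0.155 without single libraries. X-linked minus autosomal medians were -0.02 for stimulation (0.22) and 0.09 for the inhibitor (-0.02) among genes of at least 10 CPM, and -0.056 to 0.018 for the inhibitor without single libraries. For the inhibitor, unfolded protein response genes (-0.15) were at -0.027 under upper-quartile scaling, -0.117 among genes of at least 10 CPM, -0.078 with 2 libraries per group and -0.228 to -0.003 without single libraries. Erythroid markers (0.67) were at 0.659 with DESeq2 size factors and -0.374 to 0.859 without single libraries. Histone genes of the inhibitor against unstimulated cells (-0.01) were at -0.158 among genes of at least 10 CPM and -0.513 to 0.824 without single libraries. Without single libraries T cell genes ran from -0.213 to 0.101 for stimulation, -0.107 to -0.017 for the inhibitor and -0.207 to 0.101 for the inhibitor against unstimulated cells.

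With the replicate number as a replicate block, 5705 genes were higher and 6002 lower for stimulation, 3642 and 3940 for the inhibitor, and 4550 and 4575 for the inhibitor against unstimulated cells. With this block Xist for the inhibitor was at 0.36 (adjusted p = 0.0831), Trac for stimulation at 0.001 and erythroid markers for the inhibitor at 0.692. Residuals of stimulated and inhibitor libraries of the same number correlated at 0.14, 0.11 and 0.08, each library best with its own number (others at most 0.03), a hint from the data and not the design. With unstimulated libraries same-number correlations ran from -0.19 to 0, and different-number ones reached 0.14. The hint is thus no larger than some correlations between libraries of different numbers.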

Other observations

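Hypoxia response, immediate early and T cell genes were listed after the data had been seen. Their camera p-values come from the same libraries, so they describe these lists and are no independent test of them. They were adjusted over these 3 lists in the 3 comparisons alone. Genes of the hypoxia response rose with stimulation in 17 and fell in 2 of 21 (median log2 fold change 2.42, camera adjusted p = 4.8e-06, and adjusted p = 0.201 with an estimated correlation). With the inhibitor 17 fell and 1 rose (-1.43, adjusted p = 1.4e-07, and adjusted p = 0.201 with an estimated correlation). Against unstimulated cells 10 were higher and 4 lower with the inhibitor (0.50, adjusted p = 0.0385, and adjusted p = 0.541 with an estimated correlation), a call lost without unstimulated library 2 (adjusted p = 0.0751) and among genes of at least 10 CPM (adjusted p = 0.298). Besides Egln3, the adenylate kinase gene Ak4 went from 0.654 to 52.4 and 2.08 CPM in unstimulated, stimulated and inhibitor-treated cells (n = 3), and Vegfa, an angiogenic factor, from 3.77 to 81.7 and 37.2 CPM. Immediate early genes were lower in 14 and higher in 3 of 18 with stimulation (-1.95, adjusted p = 0.0038, and adjusted p = 0.541 with an estimated correlation), with Fos at 733 ± 298 and 10.4 CPM and Jun at 509 ± 181 and 23.6 CPM. With the inhibitor 8 rose and 3 fell (0.45, adjusted p = 0.257), and against unstimulated cells 2 were higher and 12 lower (-1.36, adjusted p = 7.2e-04, and adjusted p = 0.541 with an estimated correlation). The unstimulated levels were measured straight after column enrichment, and no cultured unstimulated cells are named. A raised starting level and a fall in culture therefore cannot be told apart for these genes.

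Among genes not called for stimulation, 838 were higher and 659 lower with the inhibitor than in stimulated cells; whether the changes differed was not tested. The genes named here were picked out after their values were seen, and their levels are means of 3 libraries. The lymph node homing receptor gene Ccr7 was at 248 CPM in unstimulated, 206 in stimulated and 1006 in inhibitor-treated cells, and Fam129a at 84.3, 83.0 and 361 CPM. Plac8 (84.2, 65.9 and 1.73 CPM) and the ubiquitin ligase gene Nedd4 (133, 161 and 28.1 CPM) fell. Others moved past the unstimulated level, such as the desaturase gene Scd1 (44.3, 260 and 6.65 CPM) and the transcription factor gene Myb (119, 42.0 and 229 CPM). The cholesterol exporter gene Abca1 fell in both steps (103, 29.1 and 3.72 CPM).

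The 2 tests of the rise of NF-kB targets were chosen only after that result was seen. Splits of each pair of groups into 3 and 3 libraries number 10, too few for a share under 0.05, and 1 of them, the real one, gave as many calls in each comparison. The real splits called 12126, 8182 and 9626 genes, and the highest other split called 0 in each with edgeR, with at most 238, 525 and 850 genes at an unadjusted p under 0.05. Every other split mixes the compared groups in each part, so real differences add to the spread and few calls were set in advance. The splits therefore cannot show how many calls are false.

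NF-kB target genes were higher with an inhibitor of IKK-beta, a kinase upstream of NF-kB (median 0.59, camera adjusted p = 5.7e-04, and adjusted p = 0.230 with an estimated correlation), and so were myeloid markers (2.48, adjusted p = 0.0024, and adjusted p = 0.397 with an estimated correlation). B cell markers also lay higher, without a call (1.07, adjusted p = 0.0586). The tables argue against background counts in inhibitor library 1, since the median of the targets was 0.641 without that library. More myeloid cells in the inhibitor cultures stay open, because the median rise of the 20 myeloid markers with at least 10 CPM in unstimulated cells was 0.006 of that of the 30 targets (0.187 against 30.5 CPM), but Ctss rose by 30.0 CPM. A vehicle effect stays open too, and no value measured NF-kB activity at 48 hours.

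Markers of B, myeloid, NK and erythroid cells fell with stimulation (adjusted p = 0.397, 0.208, 0.109 and 0.440 with an estimated correlation). Fewer non-T cells after culture were in line with the gap of 3.06 (log2) between the median of 12 T cell genes and the highest of the 4 marker medians. A scaling of the libraries is argued against by the T cell genes themselves, with a median of -0.08 for stimulation (2 higher and 3 lower, camera adjusted p = 0.929). Both statements rest on the same gap, so they are not separate tests. The T cell median was -0.08 for the inhibitor, with a mean of 0.04 and the test upward (3 higher and 2 lower, adjusted p = 0.929), and -0.05 for the inhibitor against unstimulated cells (1 higher and 3 lower, adjusted p = 0.929). Loss of such cells and lower expression within T cells stay open for genes that both express.

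Inhibitor library 1 had 31472 counts in 6505 of 23220 genes that had at most 2 counts in all over the other 8 libraries. RNA of another tissue would concentrate in few genes, but the top 1% of these genes held 15.5% of the counts. Evenly spread reads, such as those of genomic DNA, could explain them, yet counts in olfactory and vomeronasal receptor genes were 4.9 times those of the next library (99.1 against 20.2 CPM, here without TMM factors), just under the 5 that had been set in advance, and this stays open. That next library was unstimulated library 2, and inhibitor libraries 2 and 3 had 9.2 and 7.7 CPM. Counts were present in 722 receptor genes in inhibitor library 1, in 200 in stimulated library 1 and in 28 to 72 in the rest. Whether the treatment itself plays a part was not tested.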
